A study of Homo sapiens with 6 samples.

How the data were processed

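RNA sequencing was carried out on 6 libraries of CAL27 cells, 3 stably carrying a lentiviral CNTNAP2-203 construct and 3 carrying a control vector, each selected with 5 μg/ml puromycin for 2 weeks. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with the TruSeq RNA v2 kit, which does not mark the strand of the RNA. Reads of overlapping genes on opposite strands can therefore not be told apart. The submitters' processing notes name Trim Galore 0.4.4, a read trimmer, and the genome build hg38. The aligner, the counting tool, the gene annotation and the strand setting are not given in the sources used here. The labels of control replicate 1 say that the file of reverse reads was missing and that the forward reads were submitted as single-end, which concerns the raw reads. Whether its deposited counts were made from both reads is not given in the sources used here.

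The authors deposited 2 tables with the same genes and libraries. The first holds raw counts per gene as deposited by the authors, whole numbers for 60564 Ensembl gene identifiers, not normalized. The second holds log2 values deposited by the authors, which from their relation to the counts are log2(FPKM + 1): with an offset of 1 the gene length implied by counts and FPKM varied between libraries with a median coefficient of variation of 0.23%, and with no offset by 2.59%. How the authors handled reads that map to several genes is not given in the sources used here, so values of near-identical copies, pseudogenes and overlapping genes are uncertain. Of the listed genes 2796 had no symbol, and no row named anything other than a gene. Groups were taken from the sample titles, and the sample descriptions of the control libraries name EGFP.

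Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its defaults (minimum count 10), which left 18786 genes, libraries were scaled by TMM (factors 0.951 for CNTNAP2-203 OE replicate 3 and 0.999 to 1.02 for the others), and the groups were compared with the robust quasi-likelihood test with group as the only term. P-values were adjusted by Benjamini-Hochberg over all tested genes, at a threshold of 0.05. All adjusted p-values of single genes are from this test unless another tool is named. The common biological coefficient of variation was 0.226. SEs of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and ± gives the SD of 3 libraries. For genes with very few control counts the ratio of counts to totals is given with an exact Clopper-Pearson 95% interval, which covers counting error only. Coordinates are from GENCODE 29 (GRCh38), to which 18522 (98.6%) of the tested genes matched by identifier.

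Before the data were examined, 27 gene lists, the rule for named genes, the tests and most alternatives were fixed. The lists were E2F G1/S targets (E2F1 left out), mitosis genes, EGFR-MAPK response genes, EGFR ligands and ERBB receptors (with shedding enzymes, adaptors, ubiquitin ligases and negative regulators), p53 targets, interferon-stimulated genes, NF-kB and inflammatory cytokine genes, epidermal differentiation genes, basal squamous genes, genes of the epithelial to mesenchymal transition, YAP-TAZ targets, hypoxia genes, glycolysis enzymes, nuclear genes of oxidative phosphorylation, mitochondrially encoded genes (protein genes and both rRNA genes), cholesterol synthesis, the unfolded protein response, the ATF4 amino acid response, NRF2 targets, MYC targets in ribosome biogenesis, ribosomal proteins, replication-dependent histones, apoptosis regulators, neuronal genes, and fibroblast, leukocyte and endothelial markers. Some genes are in more than 1 list. Lists were tested with camera in limma 3.58.1 with the preset correlation of 0.01, with camera and an estimated correlation, and with fry, each adjusted over the 27 lists. Camera compares a list with the other genes, and fry asks whether its genes move, on balance, one way. Named genes were CNTNAP2, E2F1 and EGFR, the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold with a gene symbol that is no clone-style, LOC, LINC or Ensembl-style name, an average log2 CPM of at least 1 and all 3 CNTNAP2-203 OE libraries on one side of all controls, and the 3 members of each list with the smallest p. CNTNAP2 counts both as always named and among the 12 rises. Any other gene named is said to have been named after its values were seen.

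The scripts were tested on simulated counts for the 18786 genes in 3 against 3 libraries with 200 changed genes. The edgeR test recovered 4.48% of the genes changed 1.5-fold, 47.8% of those changed 2-fold and 86.4% of those changed 4-fold, and 8.91% of its calls were false. Camera called a simulated list of 60 genes changed 1.4-fold (adjusted p = 6.01e-30), and none of 26 unchanged lists was called by camera or fry. The simulated genes varied independently, so this does not test lists whose members move together. In the data the correlation estimated by camera was as high as 0.8, for the ribosomal proteins.

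The alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, limma-trend on the deposited log2 FPKM values, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library in turn, leaving out the 10 most abundant genes, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and a test against a 1.2-fold change (glmTreat). Chosen after seeing the data were the removal of GC and length trends per library (loess, span 0.3) and limma-voom with library quality weights. Chi-square per degree of freedom between libraries of one group ranged from 29.6 to 79.8, over genes with at least 10 counts, so no pair of libraries agreed within sampling noise.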

Results

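Gene expression was measured by RNA sequencing in CAL27, an established human cell line from a squamous cell carcinoma of the tongue. The cells carried either a lentivirus with CNTNAP2-203, a transcript of the gene CNTNAP2, or a control vector, and had been selected with 5 μg/ml puromycin for 2 weeks. The sample descriptions of the control libraries name EGFP. Each of the 2 groups held 3 libraries, named here CNTNAP2-203 OE (overexpression) and control. The deposited raw counts summed to 39255338, 38769375 and 41754789 in control replicates 1, 2 and 3, and to 42412703, 41005050 and 36843190 in CNTNAP2-203 OE replicates 1, 2 and 3. Between 25336 and 27002 of the 60564 listed genes had at least 1 count in a library. CNTNAP2-203 OE replicate 3 had the lowest total and the fewest genes with a count. Its distance from the other libraries of its group was 1.94 times the median of the corresponding distances of the other 5 libraries. The labels do not say whether the libraries of a group came from separate cultures or separate infections, so p-values measure only the spread between these libraries, which may be technical.

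CNTNAP2, the gene of the introduced transcript and a member of the neurexin superfamily of adhesion proteins, was close to undetected in the control cells and abundant in the overexpressing cells. Its raw counts were 0, 3 and 4 in the control libraries and 140022, 156055 and 119280 in the CNTNAP2-203 OE libraries. This corresponds to 3498 ± 248 CPM (counts per 1e6 after TMM scaling; SD, n = 3) in CNTNAP2-203 OE, and to 0, 0.0760 and 0.0947 CPM in the 3 controls. Relative to the total counts, the ratio was 59100, from 415357 against 7 counts, with an exact 95% interval of 28680 to 147000 that covers counting error only. The fitted log2 fold change of 15.81 (SE 0.374, edgeR quasi-likelihood adjusted p = 2.555e-06) depends on the prior count and is no estimate of the fold. In GENCODE 29 (GRCh38), CNTNAP2 spans chromosome 7 from 146116002 to 148420998 on the plus strand, and CNTNAP2-203 is a protein-coding transcript of 4 exons and 6076 bases at its 3′ end, from 148339461 to 148420998. The values are counts per gene, so they do not tell CNTNAP2-203 from the other CNTNAP2 transcripts.

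**Figure D1:**
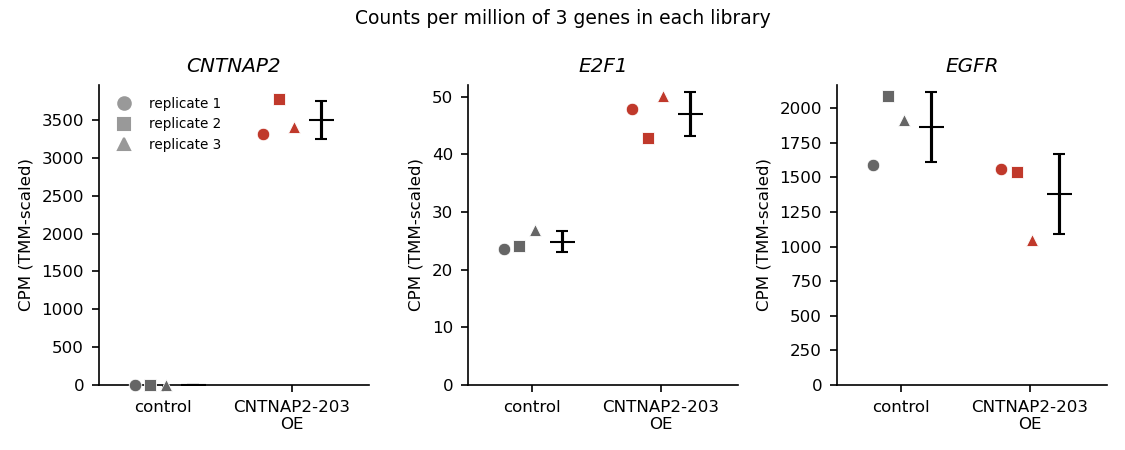
CPM (TMM-scaled, linear axes from 0) of CNTNAP2, E2F1 and EGFR in each library, with control in grey, CNTNAP2-203 OE in red and 1 symbol shape per replicate number, which does not pair the libraries; black bars give the mean and SD of 3 libraries. CNTNAP2 lies at 3307 to 3778 CPM in the 3 CNTNAP2-203 OE libraries, E2F1 at 42.8 to 50.2 against 23.5 to 27.0 CPM, and EGFR at 1047 to 1558 against 1593 to 2089 CPM.

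The series asks how CNTNAP2-203 affects the growth of oral squamous carcinoma cells, and its title names EGFR and the activity of E2F1. Across the transcriptome, 262 genes differed between CNTNAP2-203 OE and control at an adjusted p under 0.05, with 150 higher and 112 lower. Among called genes with an average log2 CPM of at least 1 and a gene symbol that is no clone-style name, the largest rises besides CNTNAP2 were in CHAMP1, which encodes a protein of chromosome alignment in mitosis, at 30.6 ± 3.20 against 3.94 ± 0.444 CPM (SD, n = 3 each), and in the cytokine gene CSF2 at 11.4 ± 2.63 against 2.32 ± 0.399 CPM. YIPF6, which encodes a Golgi membrane protein, followed at 62.0 ± 5.77 against 14.5 ± 1.06 CPM. By the same limits, the largest falls were in PGAP1, an enzyme that remodels GPI anchors, at 4.09 ± 2.32 against 32.8 ± 3.32 CPM, and in MOV10L1, an RNA helicase of the germline piRNA pathway, at 1.14 ± 0.116 against 6.14 ± 0.628 CPM.

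Further large rises were in CPA4, DKK1, CCL2, SYT16, CST6, ARHGDIB, GINS2 and C3orf33, with log2 fold changes of 1.34 to 2.03. Among them, the WNT antagonist gene DKK1 was at 95.2 ± 8.36 against 35.0 ± 0.728 CPM (log2 fold change 1.44, SE 0.102, adjusted p = 0.00234), and the chemokine gene CCL2 at 160 ± 22.7 against 60.03 ± 6.98 CPM. Further large falls, with log2 fold changes of -1.75 to -1.31, were in CLGN, KLHDC7B, ALDH1L2, CALML6, ADM2, TBL1X, NUPR1, COL21A1, TRIB3 and ABCG1. MOV10L1 (22:50089879-50161690), ADM2 (22:50481556-50486440) and KLHDC7B (22:50545891-50551023) lie near each other on chromosome 22. A copy loss or regional change there was not tested. ALDH1L2, a mitochondrial folate enzyme, was at 38.4 ± 9.26 against 114 ± 14.9 CPM, and ABCG1, a cholesterol exporter, at 7.29 ± 0.272 against 18.1 ± 1.59 CPM. CHAMP1 (13:114314335-114337626, plus strand; log2 fold change 2.96, SE 0.152, adjusted p = 0.000503) and YIPF6 (X:68498323-68537285, plus strand; 2.09, SE 0.118) varied little within groups. PGAP1 (2:196833004-196927796, minus strand; -2.99, SE 0.473) varied more, with an adjusted p of 0.0494 that stayed under 0.05 without CNTNAP2-203 OE replicate 3 and was lost without each of the other 5 libraries (0.0819 to 0.189). The same held for SYT16, C3orf33, CLGN, CALML6 and COL21A1, with adjusted p up to 0.2, 0.188, 0.133, 0.174 and 0.13, and CST6 did not pass in any of the 6 fits that leave out 1 library (0.0632 to 0.213). KLHDC7B lost its call without control replicate 2 alone (0.0539), and CSF2 and CCL2 theirs without control replicates 2 and 3 (0.0761 and 0.0667 for both). ABCG1, ADM2, ALDH1L2, GINS2, NUPR1, TBL1X and TRIB3 passed in 2 or 3 of these 6 fits, that without CNTNAP2-203 OE replicate 3 among them, and had adjusted p up to 0.0746, 0.124, 0.0828, 0.0761, 0.0839, 0.0746 and 0.133.

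The 262 calls rest on the edgeR quasi-likelihood test over 18786 genes, of which 3240 had an unadjusted p under 0.05. In all 262, the 3 CNTNAP2-203 OE libraries lay on one side of the 3 controls, which was so for 26.5% of the tested genes and would be so for 10% by chance. The test favours genes with such a separation, so for the called genes it is no added support. Of the called genes, 31 were at least 2-fold higher and 34 at least 2-fold lower. The number of calls changed when 1 library was left out. It was 18, 13 and 20 without control replicate 1, 2 or 3. Without CNTNAP2-203 OE replicate 1, 2 or 3 it was 23, 79 and 560. Fewer libraries lower the count by themselves. All 262 genes kept their direction in each of these 6 fits, which was close to fixed in advance, as their libraries lay apart by group. Of the 48 genes named by the rule that passed, 8 also passed in each of those 6 fits: ARHGDIB, CHAMP1, CNTNAP2, CPA4, DKK1, MOV10L1, TYMS and YIPF6.

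**Figure D2:**
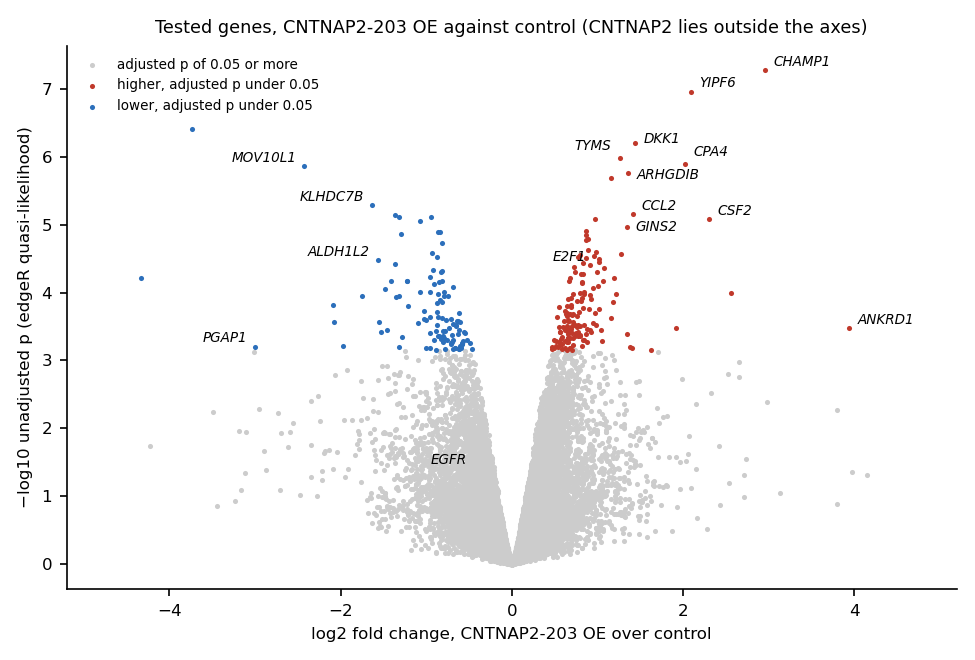
Each point is 1 of 18786 tested genes, except CNTNAP2, which lies outside the axes; the horizontal axis gives the log2 fold change of CNTNAP2-203 OE over control and the vertical axis −log10 of the unadjusted p. Red and blue points are the higher and lower genes at an adjusted p under 0.05; CHAMP1 lies at 2.96 and MOV10L1 at -2.42, while EGFR at -0.43 is among the grey points.

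E2F1, the transcription factor that drives genes of the G1/S transition, rose in CNTNAP2-203 OE together with the genes listed as its family's targets. E2F1 was at 47.0 ± 3.80 CPM against 24.9 ± 1.82 CPM (SD, n = 3 each), which is 1.89-fold. Of the 64 listed E2F G1/S targets, all tested, 32 rose and none fell, and all 64 had a positive log2 fold change, with a median of 0.66 (1.58-fold). The 3 with the smallest p were TYMS, thymidylate synthase, at 114 ± 5.46 against 47.7 ± 2.63 CPM, FEN1, the flap endonuclease of DNA replication, at 116 ± 8.09 against 59.2 ± 2.16 CPM, and GINS2, a subunit of the replicative helicase, at 49.8 ± 8.65 against 19.6 ± 0.202 CPM. With p-values adjusted over the list alone, 61 of the 64 were higher.

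The list passed with the preset correlation of camera (adjusted p = 8.76e-61), with an estimated correlation (adjusted p = 0.0194) and in fry (adjusted p = 0.000801). It was the 1 list of 27 that passed with an estimated correlation, while 15 passed with the preset one and 11 in fry. The log2 fold change of E2F1 was 0.92 (SE 0.112, edgeR quasi-likelihood adjusted p = 0.0174), with ENSG00000101412 at 20:33675683-33686404 on the minus strand. The adjusted p of E2F1 was 0.0892, 0.111 and 0.0792 without control replicate 1, 2 or 3 and 0.0839 without CNTNAP2-203 OE replicate 1. The number of E2F targets that rose was 1 without any one of the controls, 3 and 14 without CNTNAP2-203 OE replicate 1 or 2, and 41 without replicate 3. The median of the list stayed between 0.63 and 0.70 over these fits. TYMS, FEN1 and GINS2 each overlap another annotated gene, and the library kit does not mark strand.

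Genes of mitosis also rose as a group by camera (adjusted p = 5.09e-34) and fry (adjusted p = 0.0127), with an adjusted p = 0.152 with an estimated correlation. Of 65 tested, 16 rose and 1 fell, 63 had a positive log2 fold change, and the median was 0.52 (1.44-fold). The checkpoint gene MAD2L1 was at 42.5 ± 3.10 against 21.5 ± 1.72 CPM, the condensin gene NCAPG at 60.7 ± 0.991 against 34.9 ± 2.04 CPM, and CDC20, an activator of the anaphase-promoting complex, at 222 ± 16.4 against 126 ± 11.9 CPM. The member that fell was FOXM1, a transcription factor of mitotic genes, at 39.1 ± 5.61 against 67.4 ± 5.96 CPM (log2 fold change -0.78, SE 0.133, adjusted p = 0.0411); it was named after its values were seen, and it overlaps RHNO1 and ITFG2. When adjusted over the list alone, 52 were higher and 1 lower. The number of members that rose was 3 without CNTNAP2-203 OE replicate 2, 35 without replicate 3 and 26 after removal of GC and length trends, and every single-gene call was lost without any one of control replicates 1, 2 and 3 or without CNTNAP2-203 OE replicate 1.

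EGFR, the receptor named in the title, had a lower mean in CNTNAP2-203 OE that did not pass the test. It was at 1381 ± 289 CPM against 1867 ± 252 CPM (SD, n = 3 each), with a log2 fold change of -0.43 (SE 0.175, edgeR quasi-likelihood adjusted p = 0.259), although each CNTNAP2-203 OE library lay below each control. Without CNTNAP2-203 OE replicate 3 the log2 fold change was -0.27. EGFR lies at 7:55019021-55211628 on the plus strand and overlaps EGFR-AS1. Genes that respond to EGFR and MAPK signalling were lower as a group by camera (adjusted p = 0.000268) but not by fry (adjusted p = 0.12), with an adjusted p = 0.326 with an estimated correlation. The median was -0.24 over 45 tested members, of which 31 had a negative log2 fold change. Relative to the control mean, the mean log2 CPM of members was 0.06, 0.15 and -0.21 in control replicates 1, 2 and 3. It was -0.23, -0.52 and -0.27 in CNTNAP2-203 OE replicates 1, 2 and 3. Control replicate 3 thus lay near CNTNAP2-203 OE replicate 1. Without control replicate 2 the median was -0.18. The member MYC, named after its values were seen, was far higher in that library than in the others. No member passed the edgeR test over all genes, 15 had an unadjusted p under 0.05, and 8 passed by DESeq2 and none by limma-voom or limma-trend. Without CNTNAP2-203 OE replicate 3, 3 members were called lower, without control replicate 3, 1 was, and after removal of GC and length trends 4 were. The 3 with the smallest p were the phosphatase gene DUSP1 (log2 fold change -0.76, adjusted p = 0.0538), ATF3 (-1.38, adjusted p = 0.0726) and FOS (-0.63, adjusted p = 0.0776), both immediate-early transcription factors. Adjusted over the list alone, 8 were lower.

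Of 18 tested genes of EGFR ligands, ERBB receptors and proteins that act on them, which are shedding enzymes, adaptors, ubiquitin ligases and negative regulators, 1 fell: HBEGF, the heparin-binding EGF-like ligand, at 62.6 ± 10.7 against 115 ± 9.76 CPM (log2 fold change -0.88, SE 0.144, adjusted p = 0.039). With p-values adjusted over the list alone, 3 were lower and 1 higher. ADAM17 (log2 fold change -0.54) and NRG1 (0.49) did not pass over all genes. The list was lower by camera (median -0.22, adjusted p = 0.00665) and by fry (adjusted p = 0.0146), with an adjusted p = 0.152 with an estimated correlation. The HBEGF call held without CNTNAP2-203 OE replicate 3 (adjusted p = 0.0312) and was lost without each of the other 5 libraries, with an adjusted p of up to 0.168.

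Genes of the amino acid response, driven by the transcription factor ATF4, fell as a group in CNTNAP2-203 OE by camera (adjusted p = 3.88e-16) and fry (adjusted p = 0.0127), with an adjusted p = 0.152 with an estimated correlation. Of 28 tested, 8 fell and none rose, 25 had a negative log2 fold change, and the median was -0.47. WARS, a tryptophan tRNA synthetase, was at 165 ± 7.72 against 317 ± 15.7 CPM, CBS, an enzyme of cysteine synthesis, at 37.3 ± 0.689 against 65.4 ± 2.48 CPM, and the stress response gene NUPR1 at 29.7 ± 6.62 against 76.2 ± 6.92 CPM. The others that fell were AARS, SLC7A5, CEBPG and the serine synthesis genes PSAT1 and PHGDH, named after their values were seen. CBS has a near-identical copy, CBSL, between which reads can be split, and WARS overlaps WDR25. When adjusted over the list alone, 15 were lower. The number of members that fell was 3 without CNTNAP2-203 OE replicate 2 and 11 without replicate 3, and every single-gene call was lost without any one of the 3 controls or without CNTNAP2-203 OE replicate 1.

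Of 22 tested genes of the unfolded protein response, 3 fell: TRIB3 (log2 fold change -1.32, 72.7 ± 19.0 against 181 ± 8.87 CPM), which is also induced by ATF4, the sensor gene ERN1 (-0.79) and the co-chaperone gene DNAJB9 (-0.76). Adjusted over the list alone, 8 were lower and 2 higher. The list was lower by camera (median -0.24, adjusted p = 0.0282) but not by fry (adjusted p = 0.144), with an adjusted p = 0.432 with an estimated correlation, and the camera call was lost without control replicate 2 (adjusted p = 0.0685) and without CNTNAP2-203 OE replicate 1 (0.0925) or 2 (0.122, with a median of -0.15). The single-gene calls were lost without any one of the 3 controls or without CNTNAP2-203 OE replicate 1, and 1 of them stood without replicate 2. Members called higher were 1 without CNTNAP2-203 OE replicate 3 and 2 after removal of GC and length trends.

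**Figure D3:**
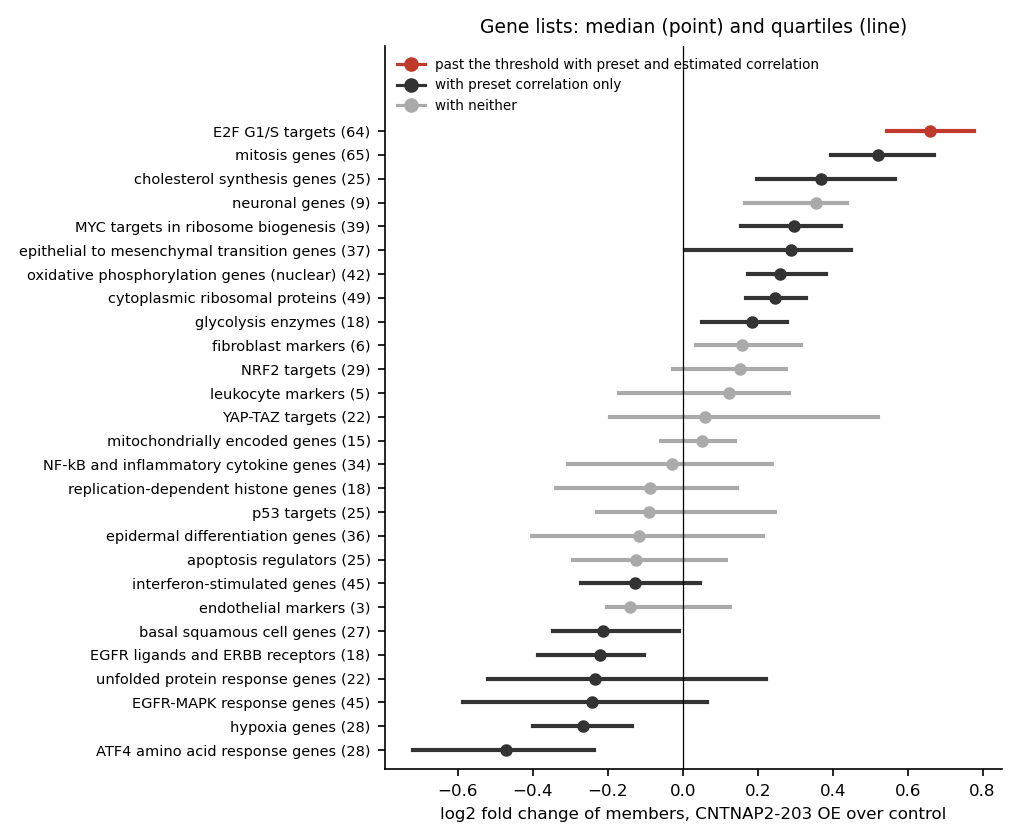
Median (point) and quartiles (line) of the log2 fold changes of the tested members of 27 gene lists, with the number tested in brackets; red passed camera with both the preset and the estimated correlation, black with the preset one only, grey with neither. The E2F G1/S targets lie highest, with a median of 0.66, and the ATF4 amino acid response genes lowest, with a median of -0.47.

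As a group, hypoxia genes were lower in CNTNAP2-203 OE by camera (median -0.27, adjusted p = 3.07e-05) and fry (adjusted p = 0.0481), with an adjusted p = 0.257 with an estimated correlation. Of 28 tested, 3 fell and none rose: the angiogenic factor VEGFA at 313 ± 30.0 against 572 ± 18.9 CPM (log2 fold change -0.87, SE 0.103, adjusted p = 0.016), NDRG1 at 179 ± 38.2 against 419 ± 46.0 CPM, and the carbonic anhydrase CA12 at 15.4 ± 1.79 against 26.9 ± 1.23 CPM. With p-values adjusted over the list alone, 8 were lower and 2 higher. The single-gene calls were lost without any one of the 3 controls or without CNTNAP2-203 OE replicate 1, 1 stood without replicate 2, and 4 members were called lower without replicate 3. After removal of GC and length trends 2 were called lower and 1 higher. The median was -0.17 without CNTNAP2-203 OE replicate 1 and -0.37 without replicate 3.

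Genes of cholesterol synthesis rose as a group by camera (median 0.37, adjusted p = 2.2e-08) and fry (adjusted p = 0.0216), with an adjusted p = 0.152 with an estimated correlation. Of 25 tested members 2 were called: ACAT2, at 152 ± 21.7 against 84.5 ± 0.802 CPM, and MVD, at 92.4 ± 5.08 against 57.3 ± 4.84 CPM. The third by p, FDFT1, squalene synthase, had a log2 fold change of 0.63 and an adjusted p of 0.0563. When adjusted over the list alone, 10 were higher. ACAT2 overlaps TCP1 and the calls of ACAT2 and MVD held only without CNTNAP2-203 OE replicate 3 among the 6 fits that leave out 1 library, with adjusted p up to 0.137 and 0.146. The median of the list was 0.56 without control replicate 3, and 4 members were called without CNTNAP2-203 OE replicate 3 and after removal of GC and length trends.

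Several lists of abundant growth and metabolism genes were higher by camera while no member passed the edgeR test over all genes. MYC targets in ribosome biogenesis had a median of 0.30 over 39 members (camera adjusted p = 3.49e-08, fry adjusted p = 0.0338, and adjusted p = 0.28 with an estimated correlation). Of these, 20 had an unadjusted p under 0.05, 7 were higher adjusted over the list alone, 6 passed by DESeq2 and none by the limma tests, and NCL, SRM and MRTO4 had log2 fold changes of 0.48, 0.61 and 0.53. Nuclear genes of oxidative phosphorylation had a median of 0.26 over 42 members (camera adjusted p = 6.59e-07, fry adjusted p = 0.181, and adjusted p = 0.481 with an estimated correlation), with 14 at an unadjusted p under 0.05, none adjusted over the list alone, 2 by DESeq2 and none by limma. ATP5G1, NDUFS3 and NDUFB3 had log2 fold changes of 0.65, 0.45 and 0.65. Glycolysis enzymes had a median of 0.19 over 18 members (camera adjusted p = 0.0112, fry adjusted p = 0.112, and adjusted p = 0.439 with an estimated correlation), with 6 at an unadjusted p under 0.05, 2 higher adjusted over the list alone, 2 by DESeq2 and none by limma, and LDHB, TPI1 and PGAM1 at 0.55, 0.59 and 0.27.

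Cytoplasmic ribosomal proteins had a median of 0.25 over 49 members (camera adjusted p = 1.62e-05, fry adjusted p = 0.318, and adjusted p = 0.524 with an estimated correlation), with 5 at an unadjusted p under 0.05 and none adjusted over the list alone or by DESeq2 or limma. RPS3, RPS15 and RPLP1 had log2 fold changes of 0.46, 0.40 and 0.42. This list stood high in CNTNAP2-203 OE replicate 3, where the mean log2 CPM of its members was 0.57 above the control mean, against 0.11 and 0.00138 in replicates 1 and 2. Without replicate 3 its median was 0.05 (camera adjusted p = 0.131), that of oxidative phosphorylation 0.11 (adjusted p = 0.00119), that of glycolysis 0.11 (adjusted p = 0.0497) and that of the MYC targets 0.19 (adjusted p = 1.2e-07), with 1 glycolysis enzyme and 1 MYC target called higher. Many ribosomal protein genes have processed pseudogenes with which reads can be shared. Mitochondrially encoded genes, with a median of 0.05 over 15 members, did not pass (camera adjusted p = 0.724), and MT-RNR1, MT-ND6 and MT-ND4L had log2 fold changes of 0.25, 0.23 and -0.27, with no member past the edgeR test, at an unadjusted p under 0.05, adjusted over the list alone, or past DESeq2 or limma. After removal of GC and length trends the list turned lower (median -0.16, camera adjusted p = 0.025), and its median was 0.08 and 0.01 without control replicates 1 and 2 and 0.03 and -0.03 without CNTNAP2-203 OE replicates 1 and 3.

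**Figure D4:**
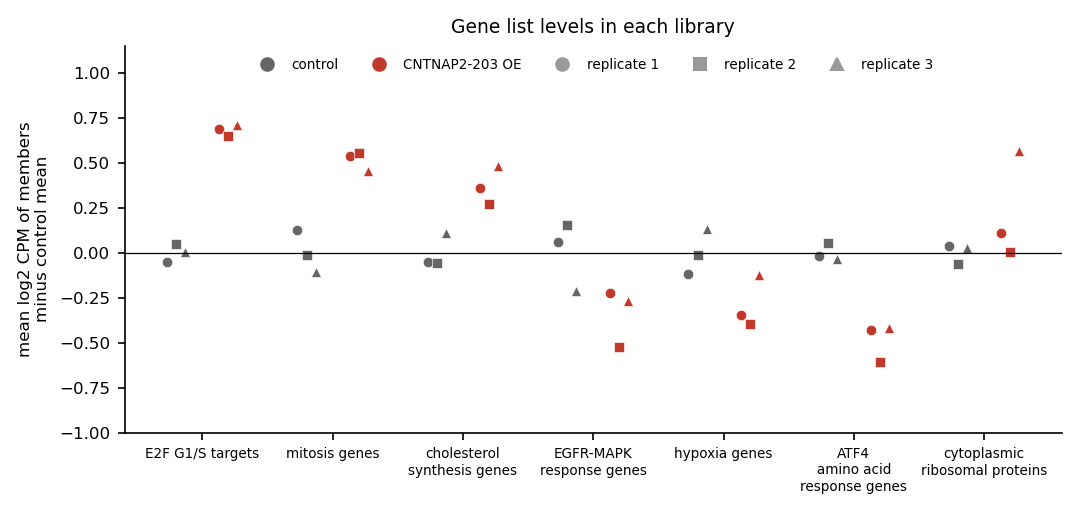
Mean log2 CPM of the members of 7 gene lists in each library, minus the mean of the 3 control libraries, with control in grey, CNTNAP2-203 OE in red and 1 symbol shape per replicate number, which does not pair the libraries. The E2F G1/S targets lie 0.65 to 0.71 above the control mean in the 3 CNTNAP2-203 OE libraries, whereas the ribosomal proteins lie 0.57 above it in replicate 3 and 0.11 and 0.00138 above it in replicates 1 and 2.

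Genes of the epithelial to mesenchymal transition were higher as a group by camera (median 0.29, adjusted p = 0.000118) and fry (adjusted p = 0.0146), with an adjusted p = 0.152 with an estimated correlation. Of 37 tested members 3 were called: the collagenase MMP13 at 80.7 ± 11.1 against 38.2 ± 3.94 CPM, the receptor kinase AXL at 85.2 ± 4.88 against 48.9 ± 5.30 CPM, and N-cadherin, CDH2, at 14.5 ± 2.26 against 6.39 ± 0.889 CPM. Adjusted over the list alone, 6 were higher and 1 lower. The number called was 7 without CNTNAP2-203 OE replicate 3, 1 without replicate 2, 0 without any one of the other 4 libraries, and 9 after removal of GC and length trends. Of 22 YAP-TAZ targets, 3 rose: AXL, which is in both lists, ANKRD1, and the tissue factor gene F3 at 1059 ± 57.2 against 715 ± 43.5 CPM. With p-values adjusted over the list alone, 5 were higher. ANKRD1 had 0, 3 and 3 counts in the controls and 29, 30 and 35 in CNTNAP2-203 OE, a ratio of 15.6 relative to total counts with an exact 95% interval of 6.91 to 43.6 for counting error only. The YAP-TAZ list did not pass camera (median 0.06, adjusted p = 0.0536) and passed fry (adjusted p = 0.0146), with an adjusted p = 0.261 with an estimated correlation. Camera called it without CNTNAP2-203 OE replicate 3 (adjusted p = 0.0495), without control replicate 2 (0.0408) and after removal of GC and length trends (0.0306). With the filter of at least 1 CPM in at least 3 libraries, which leaves out ANKRD1, its median was 0.0194 (camera adjusted p = 0.439). In that setting 2 members were called higher. The median of the list was -0.0015 and 0.09 without CNTNAP2-203 OE replicates 1 and 2 and 0.09 without control replicate 3. The calls of AXL, CDH2, ANKRD1 and F3 held only without CNTNAP2-203 OE replicate 3 among the 6 fits that leave out 1 library, and MMP13 in 2 of the 6, with adjusted p up to 0.134, 0.142, 0.167, 0.218 and 0.105.

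Inflammatory genes moved both ways. Of 34 tested targets of NF-kB and inflammatory cytokine genes, the cytokine genes CCL2 and CSF2 rose and TRAF1, a signalling adaptor, fell at 10.9 ± 0.630 against 19.1 ± 2.24 CPM. When adjusted over the list alone, 4 were higher and 3 lower. The median was -0.03 while the mean was 0.07 and the test pointed up (camera adjusted p = 0.618, fry adjusted p = 0.613). CCL2 and CSF2 each passed in 4 of the 6 fits that leave out 1 library and TRAF1 in 1, with adjusted p up to 0.0761, 0.0761 and 0.173, while 3 members were called higher and 5 lower after removal of GC and length trends, and 3 higher and 2 lower without CNTNAP2-203 OE replicate 3. Interferon-stimulated genes were lower by camera (median -0.13 over 45, adjusted p = 0.0187) and fry (adjusted p = 0.0338), with an adjusted p = 0.282 with an estimated correlation. No member passed edgeR over all genes or over the list alone, 9 had an unadjusted p under 0.05, 1 passed by DESeq2 and none by limma, and CMPK2, DDX60 and RSAD2 had log2 fold changes of -0.35, -0.46 and -0.32. The camera call was lost without control replicate 1 (0.0629) or 2 (0.0553) and without CNTNAP2-203 OE replicate 1 (0.0685) or 2 (0.056). It held without control replicate 3 (0.00535) or CNTNAP2-203 OE replicate 3 (0.00165). It also held after removal of GC and length trends (0.00129), where 1 member was called lower.

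Among genes of squamous identity, ZNF750, a transcription factor of epidermal differentiation, fell at 17.3 ± 1.17 against 36.4 ± 1.09 CPM (log2 fold change -1.07, SE 0.108, adjusted p = 0.00937). It was the 1 call among 36 epidermal differentiation genes, also adjusted over the list alone, and DSG3 and TGM1 had log2 fold changes of -0.64 and -0.51. ZNF750 passed in 3 of the 6 fits that leave out 1 library, with an adjusted p of up to 0.0761. The list did not pass (median -0.12, camera adjusted p = 0.0892, fry adjusted p = 0.194), although camera called it lower without control replicate 1 (0.0485), control replicate 2 (0.0324) or CNTNAP2-203 OE replicate 3 (0.0344), and after removal of GC and length trends (0.00764, with 3 members lower). The median was -0.02 without control replicate 3 (0.376), -0.05 without CNTNAP2-203 OE replicate 1 (0.428) and -0.08 without replicate 3. Basal squamous genes were lower by camera (median -0.21 over 27, adjusted p = 0.0145) but not by fry (adjusted p = 0.0665), with an adjusted p = 0.28 with an estimated correlation. No member passed edgeR over all genes, 9 had an unadjusted p under 0.05, 4 were lower and 1 higher adjusted over the list alone, 4 passed by DESeq2, 1 by limma-voom and none by limma-trend, and the caveolin gene CAV1 and the keratin genes KRT6B and KRT17 had log2 fold changes of 0.53, -0.45 and -0.57. Without CNTNAP2-203 OE replicate 3 the median was -0.11 (camera adjusted p = 0.0208), with 1 member called higher and 3 lower, and after removal of GC and length trends it was -0.14 (0.0398), with 1 higher and 2 lower. Keratin genes share sequence with paralogs and pseudogenes.

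Of 25 p53 targets, GDF15, a stress-induced cytokine gene, fell at 81.8 ± 10.8 against 148 ± 23.7 CPM, a call that held only without CNTNAP2-203 OE replicate 3 among the 6 fits that leave out 1 library (adjusted p up to 0.162), and PLK2 and TP53INP1 had log2 fold changes of 0.46 and -0.53. Adjusted over the list alone, 1 was higher and 1 lower. The list did not pass (median -0.09, camera adjusted p = 0.488), and its median was nearest to 0 without control replicate 1 (-0.00177) and CNTNAP2-203 OE replicate 2 (0.000286). NRF2 targets (median 0.15 over 29, camera adjusted p = 0.11), apoptosis regulators (-0.12 over 25, adjusted p = 0.307) and replication-dependent histone genes (-0.09 over 18, adjusted p = 0.325) did not pass either, and no member did by edgeR over all genes. At an unadjusted p under 0.05 were 7, 4 and 3 of their members, 2, 0 and 1 passed by DESeq2 and none by limma, and adjusted over the list alone 1 histone gene was lower. NRF2 targets were called by camera without control replicate 1 (adjusted p = 0.0369), and histone genes after removal of GC and length trends (median -0.21, adjusted p = 0.0225, with 2 members lower). With the trends removed, 1 apoptosis regulator was called lower, and of the p53 targets 1 was called higher and 1 lower. Without CNTNAP2-203 OE replicate 3, 1 NRF2 target and 1 apoptosis regulator were called lower. The NRF2 median was 0.05 in that fit and 0.09 without control replicate 2, the apoptosis median was -0.08, -0.07 and -0.05 without control replicates 1 and 3 and CNTNAP2-203 OE replicate 1, and the histone median was -0.21 and -0.02 without CNTNAP2-203 OE replicates 1 and 2. ABCC2, PRDX1 and ALDH3A1 of the NRF2 list had log2 fold changes of 0.94, 0.50 and -0.42, TNFSF10, CFLAR and BMF of the apoptosis list -0.32, -0.29 and -0.43, and HIST2H2BE, HIST1H2BK and HIST1H3D of the histone list -0.66, 0.36 and -0.71. Histone genes are near-identical copies of each other, so reads can be split between them.

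None of the tested markers of neurons, fibroblasts, leukocytes and endothelial cells passed the test. Of 22 neuronal genes, 9 could be tested, with a median of 0.36 (camera adjusted p = 0.106, fry adjusted p = 0.0481, and adjusted p = 0.3 with an estimated correlation). Camera called the list without control replicate 1 (adjusted p = 0.0425) and after removal of GC and length trends (0.0332), and the median was 0.22 without control replicate 2. The most abundant neuronal gene, TUBB3, was at 26.1 ± 2.87 against 16.7 ± 6.30 CPM, and NEFL and SYP had log2 fold changes of 0.44 and 0.44. Fibroblast (6 tested), leukocyte (5) and endothelial (3) markers had medians of 0.16, 0.12 and -0.14 and camera adjusted p of 0.477, 0.689 and 0.933. Without 1 library these medians moved by over 1.5 times, to 0.08 for fibroblast markers (CNTNAP2-203 OE replicate 3), to 0.26, 0.05 and 0.07 for leukocyte markers (control replicates 1, 2 and 3), and to -0.22 and 0.0628 (control replicates 2 and 3) and -0.09 and -0.07 (CNTNAP2-203 OE replicates 2 and 3) for endothelial markers. Named after their values were seen, the most abundant of the first 2 lists were FBLN1 at 52.2 ± 3.67 against 51.7 ± 3.12 CPM and CD68 at 33.9 ± 1.69 against 31.1 ± 4.83 CPM, and EGFL7, of the endothelial list, was at 10.6 ± 2.88 against 12.7 ± 1.46 CPM. PDGFRB, COL1A1 and COL1A2 had log2 fold changes of 0.61, -0.20 and 0.35, CORO1A, ITGAM and CD3E 0.43, 0.28 and -0.50, and CDH5, EGFL7 and VWF 0.40, -0.26 and -0.14. In these 4 lists no member passed by edgeR, DESeq2 or limma, adjusted over the list alone, or at an unadjusted p under 0.05.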

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

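Chosen after seeing the data were the removal of GC and length trends and the library quality weights; all other alternatives were planned. All 262 calls kept their direction in each alternative that tested them (256 of them with the CPM filter). This was close to fixed in advance, as their libraries lay apart by group. The number of calls moved. It was 231 to 354 under RLE, upper quartile, limma-voom, either filter choice and without the 10 most abundant genes. DESeq2 called 1063 genes (637 higher, 426 lower), 255 of them among the 262, limma-trend on log2 FPKM 165 (84 higher), removal of the trends 552 (301 higher, 251 lower), and quality weights 1020 (590 higher, 430 lower), with a weight of 0.276 for CNTNAP2-203 OE replicate 3; the causes were not tested. By their construction, stricter limits lowered it to 18 (11 and 7) at an adjusted p under 0.01, 65 (31 and 34) at an absolute log2 fold change of at least 1, and 56 (32 and 24) against a 1.2-fold change. Leaving out 1 library gave 13 to 560 calls, 8 to 323 higher and 5 to 237 lower: 18, 13 and 20 without control replicates 1, 2 and 3, 23, 79 and 560 without CNTNAP2-203 OE replicates 1, 2 and 3. Fewer libraries lower the count, yet without CNTNAP2-203 OE replicate 3, which varied most, it rose.

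With the replicate block 17 genes were called (11 higher, 6 lower), and E2F1 had a log2 fold change of 0.91 and an adjusted p of 0.0691. The numbers do not pair the libraries: deviations of same-numbered libraries correlated by -0.0824, 0.0454 and -0.0283, and 1 of the 6 libraries correlated best with its own number. E2F1 ranged from 0.86 to 0.98 when 1 library was left out and kept its call without CNTNAP2-203 OE replicate 2 or 3. Its adjusted p was 0.0892, 0.111 and 0.0792 without control replicates 1, 2 and 3 and 0.0839 without CNTNAP2-203 OE replicate 1, each with fewer libraries. CNTNAP2 passed and EGFR did not in every alternative. Lists were run with an estimated correlation and with fry on the main fit only. The block, RLE, the CPM filter, the trends removed and 1 library left out were run by camera with the preset correlation. Over all these settings the E2F list passed each time, with a camera adjusted p of 0.0194 for the estimated correlation. Mitosis genes passed in all but the estimated correlation (adjusted p = 0.152), and EGFR-MAPK response genes in all but that (0.326) and fry (0.12). Whether the E2F list passes with an estimated correlation when 1 library is left out was not tested.

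Values that changed sign were not past the edgeR or camera threshold before. After removal of the trends these were MT-ND6 (log2 fold change -0.0093), the NF-kB list (adjusted p = 0.571) and the mitochondrially encoded genes (0.025, now past it). Leaving out 1 library turned VWF (log2 fold change -0.287 to 0.0628, positive without control replicate 3), the NF-kB list (adjusted p 0.278 to 0.851, turned at 0.621), the mitochondrially encoded genes (0.27 to 0.989, turned at 0.989 and 0.621), the leukocyte markers (0.272 to 0.835, turned at 0.616) and the endothelial markers (0.676 to 0.974, turned at 0.825 and 0.874); the causes were not tested. The medians of the YAP-TAZ list, which passed fry, and the NF-kB list turned without CNTNAP2-203 OE replicate 1 (-0.0015 and 0.00362), and that of the p53 list without replicate 2 (0.000286). Depth limits genes near the filter, and with 3 libraries a group the test recovered 4.48% of simulated 1.5-fold changes, so smaller changes can lie among the genes that did not pass.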

Other observations

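The 6 gene groups of the first 2 paragraphs, the removal of GC and length trends, the test for a mislabelled library and the count of genes that stand out in 1 library were chosen after results were seen; the other tests were set before theirs. As those groups were chosen for their values, no test of a group is given, and calls are of single genes by edgeR over all genes. Of 14 tested MHC class II genes, which present peptides to T cells, 7 fell in CNTNAP2-203 OE: HLA-DRA, HLA-DRB1, HLA-DRB5, HLA-DPA1, HLA-DPB1, HLA-DQA1 and CD74, the invariant chain, which was at 569 ± 29.2 against 871 ± 49.3 CPM (SD, n = 3 each). HLA-DRA was at 180 ± 17.5 against 312 ± 27.2 CPM. The median log2 fold change was -0.72, and CIITA, the activator of these genes, had a log2 fold change of -0.57 that did not pass (edgeR adjusted p = 0.144). MHC class I genes had a median of -0.10 over 10 genes, with none called by edgeR, DESeq2 or limma. The 1 at an unadjusted p under 0.05 was HLA-C, which was higher in CNTNAP2-203 OE (log2 fold change 0.45). Reads of HLA genes can be shared between paralogs and depend on how the alleles match the reference. Without CNTNAP2-203 OE replicate 3, 9 class II genes were called lower, and without each of the other 5 libraries none was, while the median stayed between -0.80 and -0.63.

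Of 19 heat shock proteins and co-chaperones, HSP90AA1, HSPA8, STIP1 and HSPE1, which encodes a mitochondrial chaperonin, rose, and all 19 had a positive log2 fold change (median 0.46). HSP90AA1 was at 2592 ± 51.8 against 1424 ± 80.9 CPM. Of 11 tubulins, TUBA1B, TUBA1C, TUBB, TUBB4B and TUBG1 rose (median 0.65), with TUBB at 1544 ± 136 against 833 ± 35.9 CPM. Among 8 subunits of the TRiC chaperonin, which folds tubulin, TCP1 rose and the median was 0.40. TCP1 overlaps ACAT2, which was called higher as well, and the library kit does not mark strand. Among 8 LXR targets the cholesterol exporters ABCA1 and ABCG1 fell (median -0.32, and -0.20 without CNTNAP2-203 OE replicate 1). These families share sequence with pseudogenes. Without CNTNAP2-203 OE replicate 2, 2 chaperones, 1 tubulin and 1 LXR target were called, and without replicate 3 these numbers were 9, 5 and 3. No TRiC subunit was called without replicate 2, and 3 were without replicate 3. Without control replicate 3 the ABCG1 call stood (adjusted p = 0.0497); apart from that, the calls in this paragraph were lost without replicate 1 or any one control.

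E2F G1/S targets were higher in CNTNAP2-203 OE in each library. A bias with GC content or gene length as the whole cause is argued against by the removal of these trends, after which the median log2 fold change was 0.637, from 0.661. A rise carried by 1 library is argued against too, since the lowest median without 1 CNTNAP2-203 OE library was 0.633. A biological effect of CNTNAP2-203, or a difference between the 2 infected lines or in their culture, could also give it and was not tested.

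CNTNAP2-203 OE replicate 3 stood apart from its group, by 1.94 times the median distance of the other libraries. Trends with GC content and length made up 35.1% of its squared spread, but with them removed the distance was still 1.71 times the median, so they may be part of the cause and are not the whole of it. A mislabelled control is argued against by its 3409 CPM of CNTNAP2, against a mean of 3542 in replicates 1 and 2. A difference in RNA quality or library preparation stays open, as the files hold no measure of either.

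CHAMP1 and YIPF6 rose far more than the genes around them. At CHAMP1, a copy gain or regional change is argued against by the 16 tested neighbours within 1 Mb (median log2 fold change -0.015). At YIPF6, the 5 tested neighbours had a median of 0.167 (-0.328 to 0.934) and are too few to decide. The joint median was 0.007 (upper bootstrap limit 0.222), but it is set mostly by the more numerous neighbours of CHAMP1. A gain of either gene alone would not show in its neighbours. Reads of the introduced transcript that match these genes are argued against by the 0 words of 31 bases shared. Erratic counting of single genes stays open: the real split parted 4 of 8723 genes by at least 1.5 on the log2 scale (CNTNAP2, CHAMP1, YIPF6 and PGAP1), and the highest of the 9 other splits parted 3, so such counting and a change in expression cannot be told apart from these counts. A biological effect of CNTNAP2-203, or a difference between the 2 infected lines, could also give it and was not tested.

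Some abundant genes stood out in 1 or 2 libraries, chosen here after their values were seen. MYC was at 149 CPM in control replicate 2 and at 17.1 to 23.1 CPM in the other 5 libraries. B2M was at 254 CPM in CNTNAP2-203 OE replicate 2 and at 1321 to 1869 CPM in the others. CLDN4 was at 3.23 and 0.583 CPM in control replicates 1 and 2 and at 116 to 131 CPM in the other 4 libraries. Of 8723 genes with an average log2 CPM above 4, the number that lay at least 1.5 (log2) below all 5 other libraries was 2, 10 and 5 in control replicates 1, 2 and 3, and 3, 12 and 46 in CNTNAP2-203 OE replicates 1, 2 and 3, and the number at least as far above them was 0, 2 and 0, and 1, 2 and 5.

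With 6 libraries there are 10 splits into 3 against 3, so no share under 0.1 can be reached. The real split gave 262 calls, the highest of the others gave 6, and 1 of the 10 splits, the real one, reached 262.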
